A study of Mus musculus with 4 samples.

How the data were processed

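The study measured gene expression by RNA sequencing in cells of the mouse hippocampus, sorted by the fluorescence of a Vegfr3::YFP reporter. Vegfr3 is the older name of Flt4, the receptor of the growth factor VEGF-C. Per the labels, YFP-positive cells were neural stem cells of the subgranular zone (SGZ), the neurogenic layer of the dentate gyrus, and YFP-negative cells were neurons of that zone. The cells came from 2 groups of 16 C57BL/6 reporter mice. They were cultured for 18 h with or without VEGF-C at 50 ng/ml. Material from both groups of mice was pooled within each condition, which gave 4 libraries in 4 groups: YFP-positive, YFP-positive with VEGF-C, YFP-negative and YFP-negative with VEGF-C. Each group has 1 library, so no difference below has a replicate check, and no p-value was computed.

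Per the labels' protocols, libraries were made with the SMARTer Ultra Low kit, which amplifies full-length cDNA from small amounts of RNA, and sequenced as paired reads of 75 bp on a HiSeq 2500. Per the labels' protocols and the submitters' processing notes, TopHat 2.0.9, which called Bowtie 2.1.0 and used SAMtools 0.1.18, mapped the reads to mm10. The mapping was set to unstranded libraries and allowed no junctions outside the reference annotation. Expression was then estimated with Cuffdiff of Cufflinks 2.1.1. The version of that annotation is not given in the sources used here. Reads of overlapping or antisense genes cannot be told apart in unstranded data, and the estimates of near-identical copies, such as the globin genes Hba-a1 and Hba-a2, are uncertain.

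The authors deposited 2 tables with 1 value per gene and library. The first holds FPKM, per the file headers, in which fragments are scaled by transcript length and by a factor for each library. The second holds normalized counts, per the file headers, and was treated as a deposited signal because its values were not whole numbers. For a gene above 0 in all 4 libraries, the ratio of normalized count to FPKM had a median coefficient of variation across libraries of 0.23%, so both tables carry nearly the same ratios between libraries. Within a library, 99.0% to 99.6% of normalized counts below 2000 steps lay within 0.05 of a whole multiple of 1 step. Dividing by that step gave the number of fragments behind each value, here called implied fragments. These totals were 8561944 for the YFP-positive library, 60326308 with VEGF-C, 16275369 for the YFP-negative library and 8390507 with VEGF-C, a 7.19-fold range.

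Each table had 23361 rows. The symbols of 27 rows had been turned into calendar dates, as spreadsheet programs do to names such as those of the septins, and 2 of these date names stood on 2 rows each. Those rows held 0.251% to 0.317% of the normalized counts and were left out, which left 23334 rows. Symbols of 21699 rows, 93.0%, were found in GENCODE M21, which supplied gene identifiers and positions on the same build (GRCm38, mm10).

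For 2 libraries, the difference of a gene was log2((FPKM + 1) / (FPKM + 1)). This scale understates the change of genes with low values. Genes with FPKM of at least 1 in at least 1 of the libraries compared were counted as higher or lower at 2-fold or more on that scale. The comparisons were YFP-positive against YFP-negative cells without VEGF-C, the same with VEGF-C, VEGF-C against no VEGF-C in either population, and the difference between those 2 VEGF-C responses.

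An FPKM of exactly 0 can be a failed estimate. Hnrnpa1, which every cell uses, was listed at 0 in 1 library and stood at 299 to 692 FPKM in the other 3, and the reference gene Gusb was also listed at 0 in 1. Values of 0 are therefore described as listed at 0, and single genes get no fold against them in the comparisons. Such genes do enter counts, list medians and sign changes through the pseudocount of 1. Intervals and limits computed from implied fragments cover counting error only, because amplified fragments are not independent molecules.

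A total of 27 gene lists was fixed before the data were examined: VEGF ligands and receptors, neural stem cell, astrocyte, progenitor, cell cycle, immature neuron, mature neuron, oligodendrocyte precursor, oligodendrocyte, microglia, endothelium, mural cell, ependyma and choroid plexus, fibroblast, blood, immediate early, ERK feedback, stress, Notch, BMP, Hedgehog and Wnt, inflammation, interferon, cholesterol synthesis, hypoxia and glycolysis, reference and sex-linked genes. They named 429 genes, of which 424 were found, and 10 genes stood on more than 1 list. Members with FPKM of at least 1 in at least 1 of the 4 libraries counted as measured. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. The resulting percentile describes these libraries and is not a test.

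Named genes were also chosen by a rule fixed before the data were examined. It took the 10 genes per direction with the most extreme log2 ratio among protein-coding symbols with FPKM of at least 5 and a normalized count of at least 50 in 1 of the libraries compared, and with a 2-fold difference in the same direction on the normalized counts. For the populations without VEGF-C, a gene also had to differ at least 2-fold in the same direction in the pair with VEGF-C. The rule added up to 4 members per list with the largest ratios, and all VEGF ligands and receptors. Other members of a list are quoted as examples and were chosen after their values were seen. Some genes that this rule names are not reported here, though they enter the counts and list medians.

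The settings varied were a pseudocount of 0.1 or 5, no filter on low values, a filter at 5 FPKM, the normalized counts with a pseudocount of 1 and a minimum of 10, log2 ratios re-centred on the median gene, upper-quartile scaling, a 4-fold threshold, and, for the populations, the pair with VEGF-C. Added after the data were seen were a minimum mean of 20 FPKM over the 4 libraries and thinning of the implied fragments to the total of the shallowest library. The procedure was tested on simulated data drawn from the mean profile of all 4 libraries, each at its own depth. Genes were changed in the YFP-positive library without VEGF-C, which was compared with the YFP-negative one. The simulated libraries held no other difference in composition. Of 200 genes changed 2.5-fold, 80% were called, and of 200 changed 4-fold, 97.5%. The changed genes were drawn only from genes well covered in the shallowest library. These rates therefore do not describe genes with few fragments or listed at 0. Unchanged genes were called in 0.272% and 0.210% of cases, among 11412 genes, and 2 of 40 random lists fell outside the central 95% of medians. This simulation holds counting error only and not the spread between cultures. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.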

Results

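Gene expression was measured by RNA sequencing in 4 pooled libraries of hippocampal cells from Vegfr3::YFP reporter mice. In these mice, yellow fluorescent protein marks cells that use Vegfr3 (gene symbol Flt4), the receptor of the growth factor VEGF-C. The labels describe the YFP-positive cells as neural stem cells and the YFP-negative cells as neurons. Each population was cultured for 18 h without VEGF-C or with 50 ng/ml of it, and each of the 4 groups has 1 library. Every difference below is therefore a difference between 2 libraries with no replicate check.

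The libraries differed in depth and in how many genes they detected. The YFP-positive library without VEGF-C held 8561944 implied fragments and 9669 genes above 0. The YFP-positive library with VEGF-C held 60326308 fragments and 13528 genes. The YFP-negative library without VEGF-C held 16275369 fragments and 13132 genes, and the one with VEGF-C held 8390507 fragments and 9556 genes. After thinning to equal depth, the same libraries showed 9647, 12777, 12774 and 9552 genes with at least 1 fragment. The YFP-positive library without VEGF-C and the YFP-negative library with VEGF-C are called the sparse libraries below. Genes at 1 FPKM or more had median values of 24.5 and 25.4 FPKM in the sparse libraries and 10.2 and 10.3 FPKM in the others. Across 12769 genes, log2(FPKM + 1) was most alike in the libraries that are not sparse, with a Pearson's r of 0.711. The YFP-positive libraries had an r of 0.695 with each other, and the YFP-negative ones 0.690. The ribosomal RNA precursor Rn45s took 3.46% of the normalized counts of the YFP-positive library, 1.92% of the YFP-negative library and 1.51% with VEGF-C there, and was listed at 0 in the YFP-positive library with VEGF-C.

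**Figure D1:**
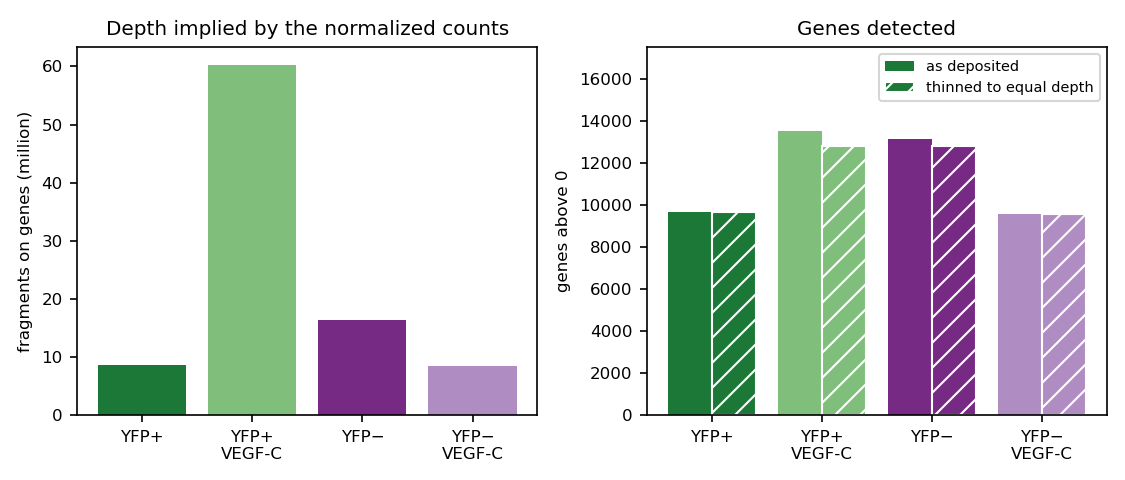
Left, implied fragments on genes in each of the 4 libraries. Right, number of genes above 0 as deposited (plain bars) and with at least 1 fragment after thinning to equal depth (hatched bars); the YFP-positive library and the YFP-negative library with VEGF-C stayed at 9647 and 9552 genes, below the 12777 and 12774 of the other 2.

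Flt4, the gene behind the reporter, lies on chromosome 11 from 49609263 to 49652739 (mm10, ENSMUSG00000020357.3, plus strand). It was listed at 0 in the YFP-positive library, where a true count of 0 would allow up to 0.0919 FPKM by the 95% exact Poisson interval. With VEGF-C, the YFP-positive library gave 2.01 FPKM from 860 fragments (same kind of interval, 1.88 to 2.15 FPKM). The YFP-negative library gave 0.0584 FPKM from 7 fragments (0.0235 to 0.120 FPKM), and with VEGF-C 0.348 FPKM from 15 fragments (0.195 to 0.575 FPKM). Flt4 was thus 5.78-fold higher in YFP-positive than in YFP-negative cells in the pair with VEGF-C. In the pair without VEGF-C Flt4 was listed at 0 in the library labelled YFP-positive, so this gene does not check that label. Kdr, the receptor VEGFR2, was at 1.02 FPKM in the YFP-positive library with VEGF-C and at 23.1 FPKM in the YFP-negative library with VEGF-C, and was listed at 0 in both libraries without VEGF-C. The co-receptor Nrp1 was at 17.4 FPKM in the YFP-positive library, 6.59 FPKM with VEGF-C and 5.16 FPKM in the YFP-negative library, and was listed at 0 there with VEGF-C. Nrp2 was at 0.187 and 2.54 FPKM in YFP-positive cells without and with VEGF-C, and at 10.8 and 1.87 FPKM in YFP-negative cells. Vegfa was at 75.9 and 10.9 FPKM in YFP-positive cells and at 10.8 and 7.82 FPKM in YFP-negative cells. Vegfb was at 6.23, 13.0, 4.67 and 21.4 FPKM in the same order. Pgf was at 1.11 FPKM in YFP-positive cells with VEGF-C and 2.45 FPKM in YFP-negative cells without it. Flt1 and Figf stayed at or below 1.15 FPKM, and Vegfc was listed at 0 in all 4 libraries.

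The first comparison asked how cells that carry the reporter differ from those that do not. Astrocyte genes were far higher in the YFP-positive library: 13 of 16 measured members were at least 2-fold higher and 0 were lower, with a median log2 ratio of 3.59. Genes of radial glia-like neural stem cells were higher too, with 14 of 19 higher, 4 lower and a median of 3.26. Oligodendrocyte genes, which encode the proteins of myelin, were far lower in YFP-positive cells, with 14 of 16 lower, 0 higher and a median of -4.92. Microglia genes were lower in 14 of 16 with 0 higher and a median of -3.73, and cytokine and chemokine genes were lower in 13 of 17 with a median of -3.88. The pair with VEGF-C, which shares no library with the first, gave medians of 4.10, 1.32, -4.50, -4.90 and -2.96 for these 5 lists. Per the labels, both pairs came from the same groups of mice, so the second is not an independent repeat.

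Among astrocyte genes, Aldoc, a glycolytic aldolase (chromosome 11, 78322968 to 78327781), was at 536 FPKM in YFP-positive and 3.30 FPKM in YFP-negative cells. With VEGF-C it was at 416 and 0.256 FPKM. Gja1, the gap junction protein connexin 43, was at 268 and 2.55 FPKM, and with VEGF-C at 285 and 0.492 FPKM. Mlc1 had a log2 ratio of 5.92. S100b went the other way in level, at 34.2 FPKM in YFP-positive and 44.7 FPKM in YFP-negative cells. The astrocyte median lay above all 10000 random lists in both pairs, and 11 of the 16 genes were at least 2-fold higher in both.

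Among stem cell genes, the transcription factor Sox9 was at 445 FPKM in YFP-positive and 5.58 FPKM in YFP-negative cells, and at 191 and 1.12 FPKM with VEGF-C. The glutamate transporter gene Slc1a3 was at 214 and 3.86 FPKM, and at 188 and 0.130 FPKM with VEGF-C. Hes5, a Notch target, was at 49.6 FPKM in the YFP-positive library, at 0.228 FPKM there with VEGF-C, and listed at 0 in both YFP-negative libraries. Msi1 was at 27.3 FPKM in the YFP-positive library and listed at 0 in the YFP-negative one. Nes, which encodes the intermediate filament nestin, was lower in YFP-positive cells, at 39.0 against 82.3 FPKM, and with VEGF-C at 43.2 against 78.0 FPKM. Sox2 was at 114 and 31.2 FPKM without VEGF-C and at 42.1 and 58.0 FPKM with it. The stem cell median stood at percentile 100 of random lists without VEGF-C and at 97.54 with it, and 8 of 19 genes were higher in both pairs.

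Oligodendrocyte and microglia genes were abundant in the libraries labelled neurons. Mbp, the myelin basic protein, was at 976 FPKM in YFP-negative and 111 FPKM in YFP-positive cells, and at 1386 and 143 FPKM with VEGF-C. Cnp was at 1110 against 36.5 FPKM, and at 1149 against 77.9 FPKM with VEGF-C. Mobp, Opalin, Gjb1 and Mag had log2 ratios of -7.32, -6.97, -6.68 and -6.64. In both pairs 13 of the 16 oligodendrocyte genes and 10 of the 16 microglia genes were lower in YFP-positive cells, and 0 were higher in both. The microglial adaptor Tyrobp was at 98.0 FPKM in YFP-negative and 0.349 FPKM in YFP-positive cells, and at 451 and 6.12 FPKM with VEGF-C. C1qb and Ctss had log2 ratios of -5.75 and -5.57. The chemokine Ccl4 was at 1030 and 5.09 FPKM without VEGF-C and at 3048 and 70.1 FPKM with it. Ccl5, Cxcl2 and Cxcl1 had log2 ratios of -7.16, -6.23 and -6.10. Both oligodendrocyte and microglia medians lay below all 10000 random lists in both pairs.

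**Figure D2:**
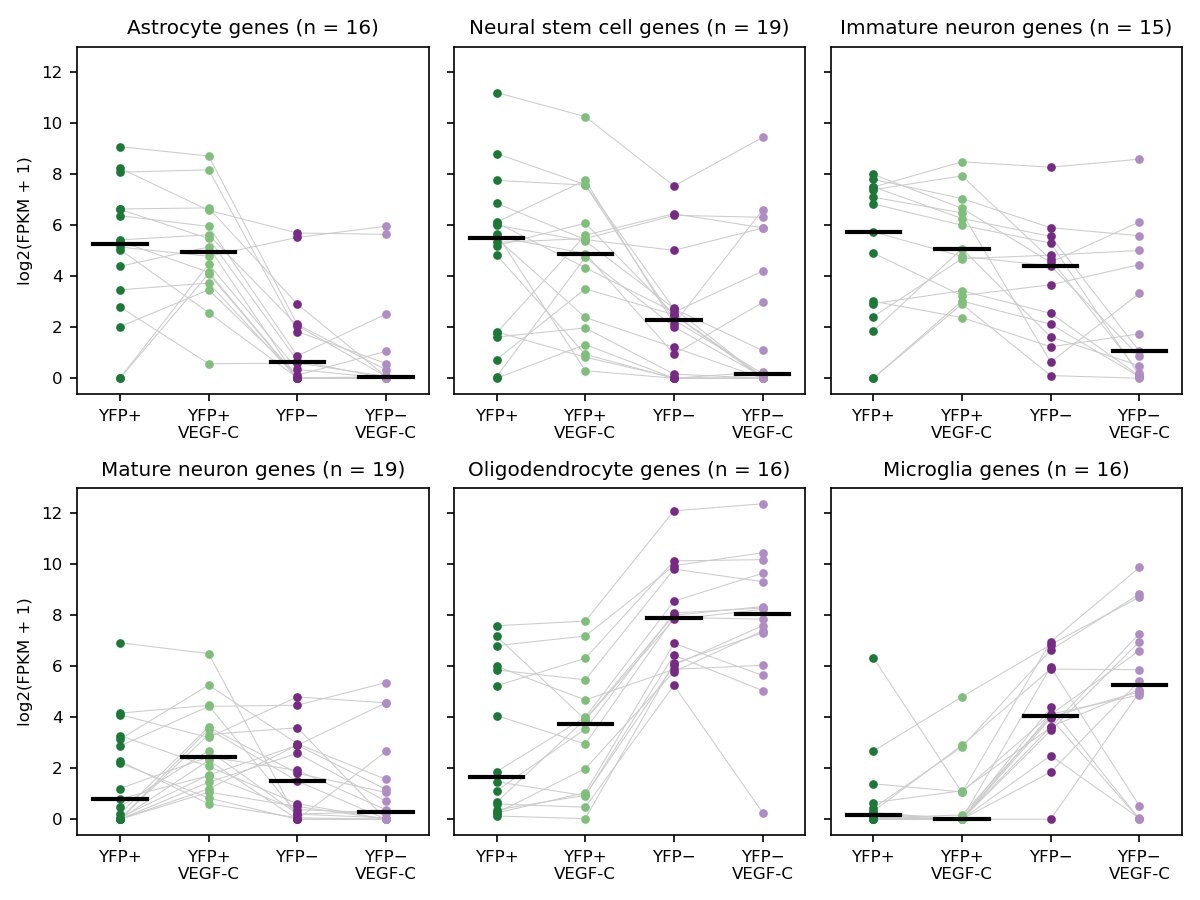
Each panel shows log2(FPKM + 1) of the measured genes of 1 list in the 4 libraries, with a point and a grey line per gene and a black bar at the median over genes. Astrocyte and stem cell genes stand higher in the YFP-positive libraries, and oligodendrocyte and microglia genes in the YFP-negative libraries, with list medians of 3.59, 3.26, -4.92 and -3.73 for the log2 ratio without VEGF-C.

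Immature neuron genes stood higher in the YFP-positive libraries, and mature neuron genes had no common direction without VEGF-C. Of 15 immature neuron genes, 9 were higher in YFP-positive cells and 2 lower. Their median of 1.33 (percentile 97.1) lay just within the central 95% of random lists. With VEGF-C, 10 were higher and 1 lower, with a median of 2.96. Neurod1, a transcription factor of newborn granule neurons, was at 135 against 0.550 FPKM, and at 88.2 against 9.03 FPKM with VEGF-C. Gap43, Tubb3 and Elavl3 had log2 ratios of 3.44, 2.73 and -2.41. Progenitor genes were higher in 8 of 15 and lower in 2, with a median of 1.35 (percentile 99.8), led by Neurod4 at 5.38 and the cyclin Ccnd2 at 4.82. Mature neuron genes were mixed, with 5 of 19 higher and 7 lower, a median of -0.50 and a mean of 0.02 (percentile 67.9), and 12 were higher and 3 lower with VEGF-C (median 2.07, percentile 95.5). The neuropeptide gene Npy was at 119 FPKM in the YFP-positive library and 88.7 FPKM there with VEGF-C, and was listed at 0 in both YFP-negative libraries. Slc17a7, the vesicular glutamate transporter of excitatory neurons, did not reach 1 FPKM in any library.

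Other lists showed smaller or less even differences without VEGF-C. BMP pathway genes were higher in 6 of 13 and lower in 3, with a median of 0.85 (percentile 98.1). Their target Id1 was at 566 against 14.9 FPKM, and at 193 against 0.350 FPKM with VEGF-C. Notch genes were higher in 7 of 12 and lower in 2 (median 1.39, percentile 98.0), with Hes1 at 4.60 and Notch2 at 3.51. Cholesterol synthesis genes were lower in 8 of 16 and higher in 3 (median -0.94, percentile 0.770), with Idi1 at -6.35. Interferon-stimulated genes were lower in 9 of 12 and higher in 1, with a median of -2.78 (percentile 0.260), but their median with VEGF-C was 0.018. Cell cycle genes were higher in 5 of 32 and lower in 10 (median -0.05, percentile 90.2), with Ccnb1 at 6.74 and Mcm5 at -4.05. In the pair with VEGF-C, cell cycle genes were higher in 25 and lower in 3, with a median of 2.78. ERK feedback genes, which receptor tyrosine kinases raise, were higher in 9 of 18 and lower in 6 (median 0.91, percentile 94.3). Spry2 among them was at 1534 against 70.3 FPKM. The remaining medians lay within the central 95% of random lists: 1.27 for hypoxia and glycolysis, 1.01 for immediate early genes, 0.66 for reference genes (mean -0.000101), 0.18 for VEGF ligands and receptors, -0.01 for Hedgehog and Wnt (mean 0.32), -0.23 for stress, -0.53 for oligodendrocyte precursors, -0.76 for endothelium, -1.31 for blood and -1.66 for mural cells. Few ependyma and choroid plexus or fibroblast genes were measured, 2 and 1, with medians of -2.89 and -1.24. Sex-linked genes had a median of -2.00 over 5 genes. Xist, the X-inactivation RNA of female cells, was at 15.3 and 7.01 FPKM in the YFP-positive libraries without and with VEGF-C, and at 0.00392 and 0.0763 FPKM in the YFP-negative ones. The Y-linked Eif2s3y was at 56.2 and 192 FPKM in the YFP-negative libraries without and with VEGF-C, and at 0.527 FPKM or listed at 0 in the YFP-positive ones.

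Of the 20 genes with the most extreme ratios that also differed in the pair with VEGF-C, Mmd2 led the higher ones, at 162 FPKM against 0.0479 FPKM (log2 ratio 7.28). Gpx8, Cd79b and the kinetochore gene Spc25 were at 138, 145 and 118 FPKM in the YFP-positive library and listed at 0 in both YFP-negative libraries. Ntpcr was at 122 FPKM against a listed 0, and Otud1 and Mgst3 had log2 ratios of 7.09 and 6.98. The lower genes were led by Sh3bgrl3, at 1.04 against 369 FPKM (log2 ratio -7.51). They also held the myelin gene Pllp at -7.30, the alarmin Il33 at -7.25, Fez1 at -7.08, Hebp1 at -6.93 and Cela1 at -6.92.

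In all, 3395 genes were at least 2-fold higher and 5257 at least 2-fold lower in YFP-positive cells without VEGF-C, among 11265 genes with a median log2 ratio of -0.66. With VEGF-C, 5278 were higher and 3103 lower among 11229 genes with a median of 0.69. The share of higher genes among those called, 39.2% without and 63.0% with VEGF-C, became 51.8% and 48.3% after re-centring, 28.0% and 73.9% with upper-quartile scaling, and 62.8% and 39.2% among genes with a mean of at least 20 FPKM. Of the lower genes without VEGF-C, 2311 were listed at 0 in the sparse YFP-positive library, and of the higher genes with VEGF-C, 2407 were listed at 0 in the sparse YFP-negative library. Across 9725 genes, which are not independent replicates, the ratios of the 2 pairs correlated with Pearson's r of 0.21 and Spearman's rho of 0.17. Of these genes, 1547 were higher in both pairs, against 1323 for independent lists, 1478 were lower in both, against 1185, and 2386 were opposite, against 2671. Agreement was closer among 3891 genes with a mean of at least 20 FPKM, where r was 0.43 and rho 0.42, 599 genes were higher in both, against 386, 601 were lower in both, against 352, and 466 were opposite, against 824.

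**Figure D3:**
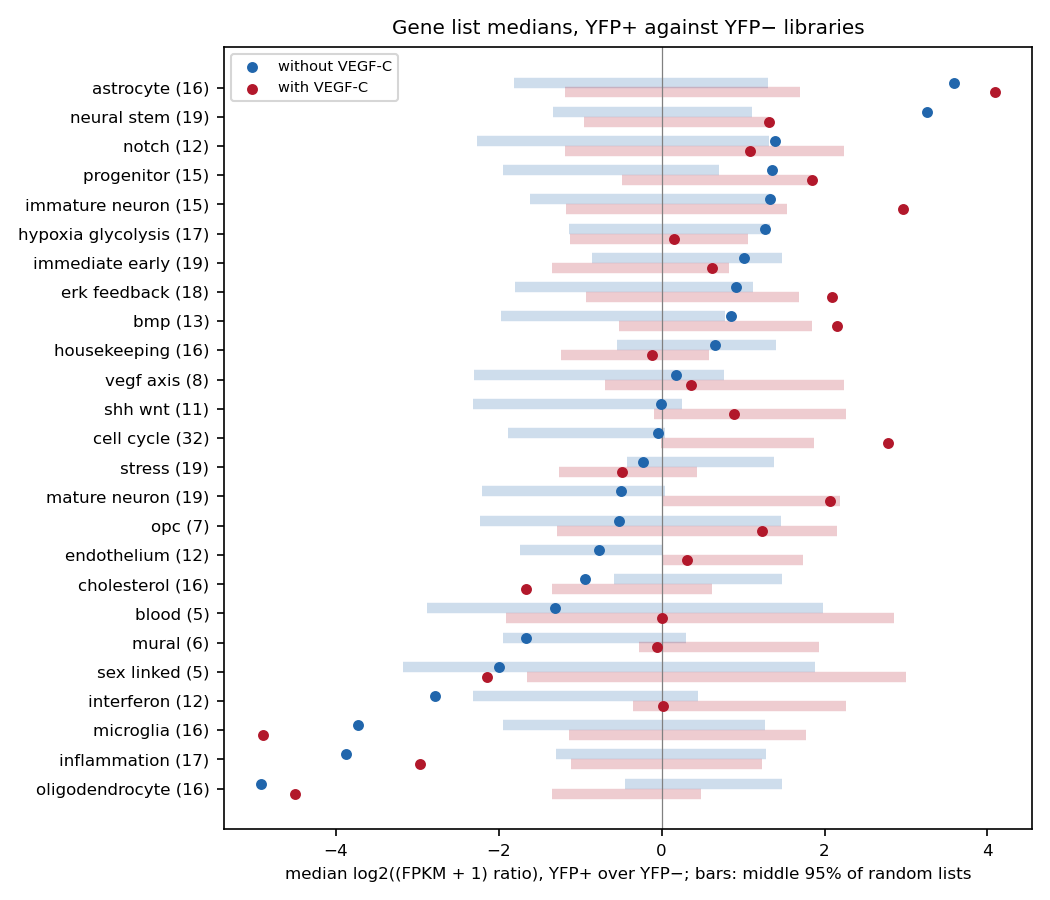
Median log2 ratio of YFP-positive over YFP-negative cells for each gene list with at least 5 measured genes (number in brackets), without VEGF-C (blue) and with VEGF-C (red). Pale bars span the central 95% of random lists of matched expression; astrocyte medians of 3.59 and 4.10 and oligodendrocyte medians of -4.92 and -4.50 lie outside them in both pairs.

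The second comparison asked how YFP-positive cells cultured with VEGF-C, the ligand of Flt4, differed from those without it. Cell cycle genes were higher with VEGF-C in 21 of 32 measured members and lower in 5, with a median log2 ratio of 2.11. Cytokine and chemokine genes were higher in 9 of 17 and lower in 4, with a median of 1.48. ERK feedback genes were higher in 9 of 18 and lower in 0, with a median of 1.04. Over members with a mean of at least 20 FPKM, the ERK feedback median was -0.59 (9 genes) and the cytokine median 0 (11 genes). Astrocyte and stem cell genes showed no common direction, with medians of -0.16 (mean 0.09) and -0.62. The library without VEGF-C is one of the sparse libraries, and 2174 genes listed at 0 in it were among those higher with VEGF-C.

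Cell cycle genes that were higher included Ube2c, a ubiquitin-conjugating enzyme of mitosis, at 26.3 FPKM with and 0.183 FPKM without VEGF-C. The DNA methylation factor Uhrf1 was at 18.5 and 0.0872 FPKM, and the replication factor Gins2 at 21.6 and 0.322 FPKM. Mcm2 to Mcm7, the subunits of the replicative helicase, were all higher in level, among them Mcm7 at 54.3 against 9.11 FPKM and Mcm5 at 16.0 against 0.0867 FPKM. The proliferation marker Mki67 was at 3.06 FPKM with VEGF-C and listed at 0 without it. The 5 lower members, Pcna, Ccnb1, Kif11, Slbp and Plk1, were the most abundant ones without VEGF-C. Pcna was at 56.2 against 273 FPKM, Ccnb1 at 8.11 against 127 FPKM and the kinesin Kif11 at 0.251 against 69.6 FPKM. The list median stood at percentile 99.8 of random lists. It was -0.73 over the 4 members with a mean of at least 20 FPKM.

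Stem cell genes were higher in 5 of 19 and lower in 6. Hes5 and Msi1 had log2 ratios of -5.36 and -3.89, and Vcam1 and Lpar1 of 4.68 and 3.83. Fabp7 was at 214 FPKM with and 68.2 FPKM without VEGF-C, and Sox9 at 191 and 445 FPKM. Progenitor genes were higher in 5 of 15 and lower in 4 (median -0.20, mean 0.12). Neurog2, a transcription factor of intermediate progenitors, was at 2.60 FPKM with VEGF-C and listed at 0 without it, and Neurod4 had a log2 ratio of -4.38. Immature neuron genes were higher in 4 of 15 and lower in 3, with a median of -0.61 and a mean of 0.36. Mature neuron genes were higher in 12 of 19 and lower in 3, and their median of 1.24 stood at percentile 74.5 of random lists.

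Among ERK feedback genes, Dusp5, a phosphatase of ERK, was at 11.7 FPKM with and 0.853 FPKM without VEGF-C. Dusp4 and Etv1 were at 13.0 and 9.15 FPKM with VEGF-C and listed at 0 without it. Spry2 was lower in level, at 782 against 1534 FPKM. That list's median stood at percentile 93.2, within the central 95% of random lists. Cytokine genes included Ccl5 with a log2 ratio of 3.87 and Ccl4 with 3.55, and Ccl3 with -3.95 and Cd14 with -3.37, at percentile 99.2. Oligodendrocyte genes were higher in 5 of 16 and lower in 3, with a median of 0.28 at percentile 97.6, which was -0.31 after re-centring. Interferon genes were higher in 6 of 12 (median 0.62), Notch genes in 5 of 12 (median -0.00369) and immediate early genes in 4 of 19, with 8 lower (median -0.85). These 3 medians lay within the central 95% of random lists.

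The genes with the highest ratios were led by Atp6v1f, a subunit of the vacuolar proton pump, at 168 against 0.298 FPKM (log2 ratio 7.03). Ndufb3, Mrps28 and Pam16, which encode mitochondrial proteins, had log2 ratios of 6.27, 6.23 and 6.13, and Sh3bgrl3, Snrpn and Sar1b of 6.16, 6.06 and 6.01. Acyp2, Lxn and Dnajc15 were at 76.9, 67.4 and 66.1 FPKM with VEGF-C and listed at 0 without it. In the opposite direction, S100a8, Wfdc18 and Cast were at 120, 83.3 and 75.4 FPKM without VEGF-C and listed at 0 with it. Gng13, Ccdc102a, Cd300ld, Dnd1 and Necab2 had log2 ratios of -6.79, -6.54, -6.45, -6.41 and -6.40.

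In all, 5020 genes were at least 2-fold higher and 2899 at least 2-fold lower with VEGF-C in YFP-positive cells, among 11040 genes with a median log2 ratio of 0.59. Of the lower genes, 130 were listed at 0 with VEGF-C. The share of higher genes, 63.4%, became 48.3% after re-centring, 76.6% with upper-quartile scaling and 38.1% among genes with a mean of at least 20 FPKM.

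The third comparison put the same question to YFP-negative cells. Microglia genes were higher with VEGF-C in 9 of 16 measured members and lower in 4, with a median log2 ratio of 1.66. Interferon-stimulated genes were lower in 9 of 12 and higher in 3, with a median of -2.98. Oligodendrocyte genes, the most abundant cell type genes in these libraries, were about level, with 4 of 16 higher, 3 lower, a median of 0.24 and a mean of -0.05. Cell cycle genes were lower in 12 of 32 and higher in 4, with a median of -0.48. Here the library with VEGF-C is the sparse one.

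Microglia genes included Fcrls, at 30.4 FPKM with VEGF-C and listed at 0 without it, and Trem2, at 96.3 against 16.2 FPKM. Tyrobp was at 451 against 98.0 FPKM and Fcer1g at 930 against 123 FPKM. The complement genes went the other way: C1qb was at 0.437 against 61.2 FPKM, and C1qa and C1qc were at 14.5 and 19.8 FPKM without VEGF-C and listed at 0 with it. The list median stood at percentile 99.98 of random lists. Among interferon genes, Isg15, Irf7 and Mx1 were at 46.1, 13.8 and 11.6 FPKM without VEGF-C and listed at 0 with it, and Bst2 had a log2 ratio of -4.40. Ifitm3 was higher, at 276 against 53.2 FPKM. The interferon median stood at percentile 0.0400.

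Cytokine genes were higher in 5 of 17 and lower in 3, with a median of 0.10 and a mean of -0.15. Il6 had a log2 ratio of 2.93, and Ccl2 and Cxcl10 of -5.71 and -3.14. Immature neuron genes were lower in 7 of 15 and higher in 2 (median -0.31), with Stmn2 at -5.19, Dpysl3 at -4.50 and Tubb3 at -4.43. BMP genes were lower in 5 of 13 and higher in 0 (median -0.07), with Id3 at -5.51 and Id1 at -3.56. ERK feedback genes were lower in 6 of 18 and higher in 2 (median -0.66), with Dusp4 at 68.8 FPKM with and 2.10 FPKM without VEGF-C. Over members with a mean of at least 20 FPKM, the ERK feedback median was 0.27. Spry1 was at 6.40 FPKM without VEGF-C and listed at 0 with it. Stem cell genes had a median of -0.08, and Fabp7 among them was at 95.8 against 3.36 FPKM. These lists, and cell cycle genes, lay within the central 95% of random lists.

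The genes with the highest ratios were led by Chchd6, at 244 against 0.488 FPKM (log2 ratio 7.36). Fabp3, Ppp1r27, the tight junction gene Cldn10, Mgst2 and H2-M3 were at 148, 136, 112, 111 and 97.5 FPKM with VEGF-C. All were listed at 0 without it. Abhd14b, Gtf2h4, Rab13 and Rbks had log2 ratios of 6.57, 6.53, 6.53 and 6.51. In the opposite direction, the splicing factor Hnrnpa1, Coa3 and Cox19 were at 299, 87.2 and 81.4 FPKM without VEGF-C and listed at 0 with it. The pituitary hormone gene Prl was at 103 FPKM without VEGF-C and 0.179 FPKM with it, and was listed at 0 in both YFP-positive libraries. Trappc2l, Dctn5, Aurkaip1, Tmem97, Ndufv1 and Med6 had log2 ratios of -6.46, -6.29, -6.28, -6.21, -6.17 and -6.06.

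In all, 2780 genes were at least 2-fold higher and 4969 at least 2-fold lower with VEGF-C in YFP-negative cells, among 10968 genes with a median log2 ratio of -0.54. Of the lower genes, 2136 were listed at 0 with VEGF-C, and of the higher genes, 155 were listed at 0 without it. The share of higher genes, 35.9%, became 50.0% after re-centring, 22.7% with upper-quartile scaling and 63.0% among genes with a mean of at least 20 FPKM.

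**Figure D4:**
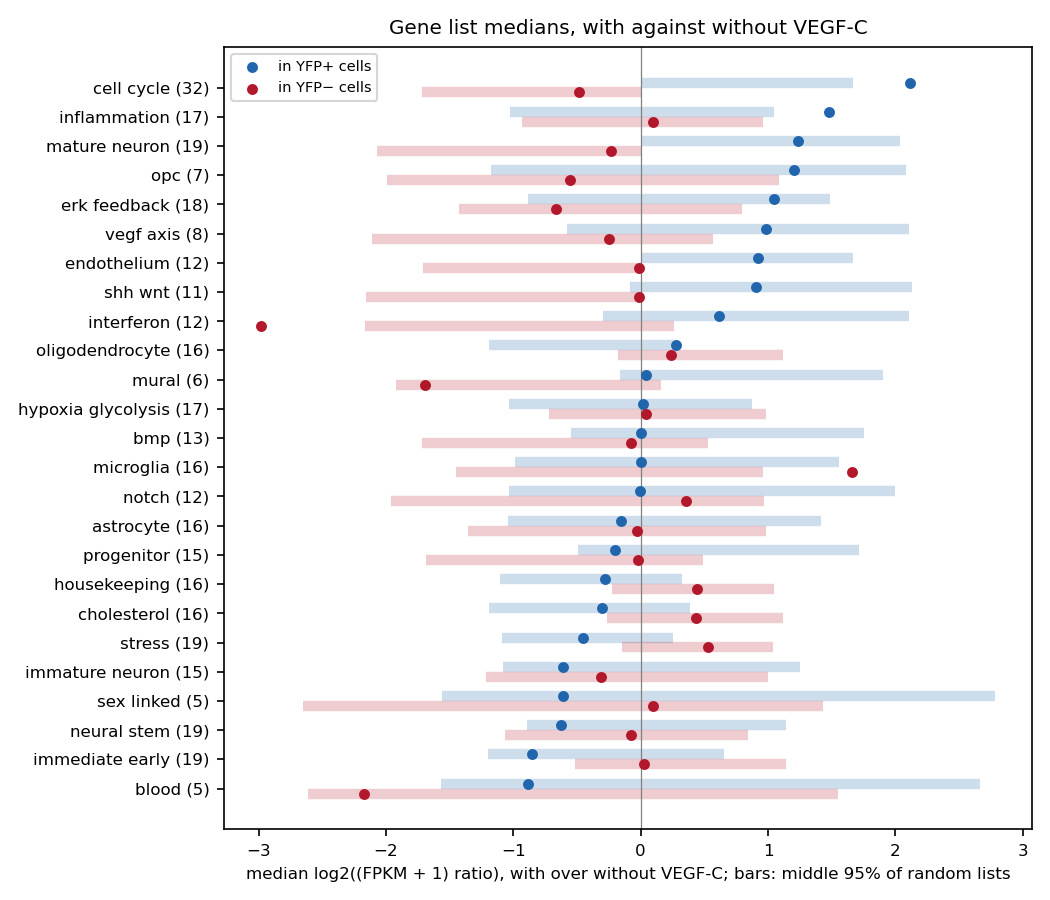
Median log2 ratio of cells with over without VEGF-C for each gene list with at least 5 measured genes (number in brackets), in YFP-positive (blue) and YFP-negative cells (red). Pale bars span the central 95% of random lists of matched expression; the cell cycle median of 2.11 in YFP-positive cells and the microglia and interferon medians of 1.66 and -2.98 in YFP-negative cells lie outside them.

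The last comparison set the VEGF-C difference of YFP-positive cells against that of YFP-negative cells. Cell cycle genes had the more positive difference in YFP-positive cells, with 21 of 32 differences of at least 1, 7 of at most -1 and a median difference of 3.02 on the log2 scale. Interferon genes had a median difference of 3.79, with 9 of 12 positive and 1 negative at that size. Immature neuron genes had a median of 2.58 and a mean of 1.54, with 9 of 15 positive and 4 negative. Their medians with VEGF-C were below 0 in both populations, at -0.61 in YFP-positive and -0.31 in YFP-negative cells. Notch genes had a median of -1.85 and a mean of -0.55, with 5 of 12 positive and 7 negative. The median differences of these lists stood at percentiles 99.4, 99.6, 99.3 and 0.680 of random lists, and the cell cycle median difference was -0.87 over the 4 members with a mean of at least 20 FPKM.

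Single genes behind these values included Ube2c and Mcm5, with differences of 8.41 and 8.08, Tubb3, with 4.97, and Notch1, with -4.29. Mcm2, Bst2, Isg15, Bhlhe22 and Hes5 were each listed at 0 in at least 1 library. The most positive differences belonged to Aurkaip1, Med6, Hsd17b10, Tmem97 and Pdzd11, from 11.95 to 10.47, and to Acyp2, Ube2f, Nudt21, Ddt and Gal, which were listed at 0 in at least 1 library. Each of these genes was at 1.19 FPKM or less, or listed at 0, in both sparse libraries. The most negative included Chchd6 at -11.64 and Gpr146 at -8.81, Rlf, the cell cycle regulator E2f1, Grk4, Arap1 and Fcer1g, from -8.61 to -8.19, and Wfdc18 and Zbtb46, which were listed at 0 in 1 library. Counts and medians include differences of genes listed at 0 in a library, which rest on the pseudocount of 1. In all, 6604 genes had a difference of at least 1 and 3502 of at most -1, among 12769 genes with a median of 1.11. The share of positive differences, 65.3%, became 46.8% after re-centring, 79.5% with upper-quartile scaling and 38.2% among genes with a mean of at least 20 FPKM.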

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

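The tests of sequencing depth and of swapped population labels were chosen after their results had been seen.

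For 3 gene lists with at least 5 measured genes, the medians with VEGF-C had opposite signs in the 2 populations and their difference lay outside the central 95% of random lists. None of these differences was tested, since each rests on 4 single libraries. Cell cycle genes differed by a median of 3.02 on the log2 scale, with medians of 2.11 in YFP-positive and -0.48 in YFP-negative cells, the latter 0.056 after re-centring. Over the 4 members with a mean of at least 20 FPKM, the difference was -0.87 and the median in YFP-positive cells -0.73. Interferon genes differed by 3.79, with medians of 0.62 and -2.98, the first -1.06 over the 2 genes with a mean of at least 20 FPKM, where both medians were below 0. Notch genes differed by -1.85, with medians of -0.00369 and 0.36, the first about 0 and so without a direction. Other lists also had medians of opposite signs, such as ERK feedback (1.04 and -0.66) and mature neuron genes (1.24 and -0.23), but differences within that range. With a mean of at least 20 FPKM both ERK feedback medians changed sign, to -0.59 and 0.27. The mature neuron median in YFP-negative cells was 0.31 after re-centring and 0.44 over 2 genes with that mean. Of 9239 genes measured in both comparisons, 2606 were at least 2-fold apart in opposite directions, against 2244 for independent lists. Of them, 1930 were higher with VEGF-C in YFP-positive cells, against 1620, and 676 lower, against 624. Among 3828 genes with a mean of at least 20 FPKM, 568 were opposite, against 646.

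Both short RNA genes below had very high FPKM in the YFP-negative library without VEGF-C and were listed at 0 in the other 3 libraries. Mir5136 was at 73901 FPKM from 2 implied fragments, and Snord96a at 28588 FPKM from 3. These entries were outside the comparisons of named genes.

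The first pattern is that the YFP-positive library without VEGF-C and the YFP-negative library with VEGF-C list fewer genes than the other 2. The tables argue against depth as the whole explanation, because at equal depth the YFP-positive library with VEGF-C still listed 1.32 times as many genes as the one without, and the YFP-negative library without VEGF-C 1.34 times as many as the one with it. Loss of transcripts at random, as may happen when a small amount of RNA is amplified, stays open. Of 570 genes at 10 to 20 FPKM in both fuller libraries, 28.1% were under 1 FPKM in one sparse library and 30.4% in the other. In both there were 63, against 48.6 for independent loss, a ratio of 1.30 (95% bootstrap interval over genes 1.101 to 1.514). Joint loss was thus more frequent than fully independent loss, for which the ratio is 1. The interval also reaches past 1.5, the bound above which loss at random would have been set aside, so the test does not decide. No biological explanation was tested, and since the sparse libraries sit on opposite sides of the design, the pattern enters both VEGF-C comparisons with opposite signs and their difference with both.

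The second pattern is the abundance of oligodendrocyte and microglia genes in the libraries labelled neurons. A swap of labels within the pair without VEGF-C is argued against by the oligodendrocyte medians of the 2 pairs, whose product was 22.2 and would be negative after such a swap. For a swap in both pairs, the log2 ratios of the 19 stem cell genes, averaged over both pairs, had a median of 2.24 (95% exact interval over genes 0.87 to 3.33). They were above 0 for 17 genes and below for 2. These genes do not decide on such a swap, because astrocyte genes were also higher in the libraries labelled YFP-positive, with medians of 3.59 and 4.10. The stem cell list does not separate stem cells from astrocytes. Flt4 alone does not decide on a swap in both pairs either, with 7.97 times more fragments per unit of depth in the library labelled YFP-positive in the pair with VEGF-C (4.81 to 14.3, counting error only), and in the pair without it a listed 0, which may be a failed estimate, against 7 fragments. A candidate explanation that was not tested is that sorting by absence of YFP collects every cell without the reporter, glia included. It would have to account for Mbp at 976 and 1386 FPKM beside 21.1 and 39.9 FPKM of the synaptic gene Snap25. It would also have to account for the low astrocyte genes, whose list median was 0.562 FPKM in the YFP-negative library and 0.0466 FPKM there with VEGF-C.

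The third pattern is the split of sex-linked genes, with Xist high in the YFP-positive libraries and Eif2s3y in the YFP-negative ones. Random dropout of single genes is argued against for Eif2s3y: among 506 genes within 2-fold of it in both YFP-negative libraries, 9 were under 1 FPKM in both YFP-positive ones, or 1.78% (95% exact interval 0.816 to 3.35), below the bound of 5%. For Xist dropout stays open, because this test cannot decide it. Of 811 matched genes, 35, or 4.32% (3.02 to 5.95), were under 0.1 FPKM in both YFP-negative libraries, an interval that includes 5%. Such genes may include those that the populations use differently, so that share is not a rate of dropout. The YFP-negative library without VEGF-C, which is not a sparse one, held 1 Xist fragment, against 1359 and 9374 in the YFP-positive libraries. Ddx3y, also Y-linked, was at 18.7 and 0.700 FPKM in the YFP-positive libraries and at 36.2 and 6.50 FPKM in the YFP-negative ones, Kdm5d was listed at 0 and at 0.00250 FPKM against 5.40 and 7.67 FPKM, and Uty was at 3.00 FPKM in the YFP-negative library without VEGF-C and listed at 0 in the other 3. A different mix of male and female mice behind the 2 populations was not tested, since the labels give no sex. It would be at odds with the labels, by which material from both groups of mice was pooled within each condition. The design as described does not account for the split.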

How the results depend on the processing

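The minimum mean of 20 FPKM and the thinning to equal depth were chosen after the data had been seen. Each group has 1 library, so no fit that pairs replicates was made and no library was left out. Every count stayed within 1.5 times its value with no filter, a pseudocount of 0.1, the normalized counts, re-centring and thinning to equal depth. Even so, re-centring changed which side was larger in every comparison except VEGF-C in YFP-negative cells, where it left 3938 genes on each side. Of 108 list medians, 32 kept 1 sign under all their alternatives, among them in the populations without VEGF-C the astrocyte (2.49 to 5.74), neural stem (1.32 to 3.92), oligodendrocyte (-5.80 to -3.78), microglia (-6.85 to -1.83) and inflammation (-7.28 to -1.90) medians. In YFP-negative cells the medians of microglia (0.87 to 2.504) and interferon genes (-5.47 to -1.31) with against without VEGF-C did so too. Those alternatives all use the same pair of libraries, of which the one with VEGF-C is sparse, so they do not separate VEGF-C from other differences between the libraries. Depth limits what can be said of genes with few fragments. The causes of the shifts below were not tested, except that stricter filters and thresholds leave fewer genes.

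Counts are given as higher and lower for YFP-positive against YFP-negative cells without VEGF-C, VEGF-C in YFP-positive cells, VEGF-C in YFP-negative cells, the difference of those responses, and the populations with VEGF-C, where they moved by more than 1.5 times. With a mean of at least 20 FPKM they were 1628 and 965, 865 and 1403, 1359 and 797, 1076 and 1739, and 935 and 1453, so that the larger side changed in all 5. At 4-fold they were 1835 and 3500, 3093 and 1267, 1273 and 3062, 2047 lower for the difference, and 3398 and 1670. With a pseudocount of 5 they were 3140 lower, 2716 higher, 2713 lower, 3966 higher and 3045 higher. With FPKM of at least 5, and no such shift in the difference, they were 3420 lower, 3065 higher, 3032 lower and 3338 higher. With upper-quartile scaling the VEGF-C counts were 1818 lower in YFP-positive cells, 1717 higher in YFP-negative cells and 2075 lower for the difference.

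The cell cycle median with VEGF-C in YFP-positive cells was 4.78 and 0.80 with pseudocounts of 0.1 and 5, 5.45 on the normalized counts and -0.73 with a mean of at least 20 FPKM. In YFP-negative cells it was 0.056 after re-centring, and the difference was -0.87 with a mean of at least 20 FPKM. For the populations without VEGF-C, the astrocyte median was 5.74 on the normalized counts and the oligodendrocyte median -3.78 with a pseudocount of 5. The microglia median was -5.60 and -1.83 with pseudocounts of 0.1 and 5, -6.85 on the normalized counts and -4.90 in the pair with VEGF-C. The mature neuron median was 2.65 over 2 genes and the interferon median 0.21 over 2 genes with a mean of at least 20 FPKM, and the interferon median was 0.018 in the pair with VEGF-C. The oligodendrocyte median with VEGF-C in YFP-positive cells was -0.31 after re-centring. With a mean of at least 20 FPKM, the ERK feedback median was -0.59 with VEGF-C in YFP-positive and 0.27 in YFP-negative cells, and the median difference -0.69, over 9 genes. With that filter the interferon median in YFP-positive cells was -1.06 over 2 genes.

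The log2 ratios of 25 named genes changed sign in the pair with VEGF-C. They were above 0 there for Hba-a2 (5.07), Hes6 (4.53), Mcm5 (4.03), Dhcr7 (3.65), Stx1a (3.32), Dll1 (2.41), Vcan (2.27), Spry1 (2.18), Tbp (2.16), Bst2 (1.86), Igf2 (1.31), Foxj1 (1.28), Cdh5 (1.12), Pgf (1.08), Nrp2 (0.30), Pdgfrb (0.089), Rgs5 (0.080), Irf7 (0.035), C1qc (0.021) and Gad1 (0.021). They were below 0 for Olig2 (-3.83), Bbc3 (-2.86), Nsdhl (-0.93), Kif11 (-0.59) and Vtn (-0.12). Of these, Rgs5, Pdgfrb, Irf7, C1qc and Vtn were under 1 FPKM or listed at 0 in both libraries with VEGF-C, and Gad1 was at 1.28 and 1.24 FPKM, so their signs show no reversal. The ratios of Hes6, Stx1a, Dll1, Vcan, Spry1, Igf2, Foxj1, Cdh5 and Pgf in that pair rest on the pseudocount of 1, since each was listed at 0 in the YFP-negative library. The sparse libraries stand on opposite sides of the pairs, so a value near 0 in both is enough to change the sign. Mcm5, for example, was under 1 FPKM in both sparse libraries, so its change of sign shows no reversal between the populations.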

Other observations

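The values and tests in this part were chosen after the data had been seen, although Lef1, Dusp4 and Cldn10 also met the rule for named genes. Among genes on no list of the report, several were higher in YFP-positive cells in both pairs of libraries. Inhba, which encodes the activin A subunit, was at 438 FPKM in YFP-positive and 4.42 FPKM in YFP-negative cells, and at 133 and 0.192 FPKM with VEGF-C. The endothelin receptor gene Ednrb was at 142 against 2.20 FPKM and at 44.5 against 0.0343 FPKM with VEGF-C. The proteoglycan gene Ncan was at 118 against 3.37 FPKM and at 89.4 against 0.0940 FPKM. The transcription factor gene Lhx2 was at 36.8 FPKM, or 42.7 FPKM with VEGF-C, against a listed 0 and 0.0619 FPKM. In the other direction, Ptgds, the prostaglandin D synthase, was at 3275 and 5574 FPKM in YFP-negative cells without and with VEGF-C, and at 81.4 and 153 FPKM in YFP-positive cells. The antigen presentation gene Cd74 was at 92.1 and 251 FPKM against 0.665 and 3.42 FPKM, and the lipase gene Lpl at 120 and 240 FPKM against 2.58 and 1.63 FPKM.

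Genes that differed with VEGF-C overlapped between the 2 populations about as often as independent lists would. Across 9239 genes the log2 ratios of the 2 responses, which share no library, had a Pearson's r of -0.06 and a Spearman's rho of -0.07. There were 1004 genes higher with VEGF-C in both, against 1002 for independent lists, and 937 lower in both, against 1009. The overlap was larger among 3828 genes with a mean of at least 20 FPKM, where r was 0.14, 406 genes were higher in both against 294, and 366 were lower in both against 282. Genes higher in both included the Wnt pathway factor Lef1, at 14.3 and 49.9 FPKM with VEGF-C in YFP-positive and YFP-negative cells and listed at 0 and at 0.0443 FPKM without it. The ERK phosphatase gene Dusp4 was at 13.0 and 68.8 FPKM with VEGF-C and listed at 0 and at 2.10 FPKM without it, and Cldn10 was at 39.9 and 112 FPKM with VEGF-C and listed at 0 in both without it.

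Fth1, Ftl1 and Hmox1 were abundant in all 4 libraries. The ferritin gene Fth1 was at 15214 and 11289 FPKM in YFP-positive cells without and with VEGF-C, and at 29043 and 45972 FPKM in YFP-negative cells. Ftl1 was at 15694 and 13211 FPKM, and at 11320 and 17137 FPKM. Hmox1, the heme oxygenase, was at 6693 and 6731 FPKM, and at 2202 and 3031 FPKM.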
